A study of Rattus norvegicus with 24 samples.

How the data were processed

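RNA from the abdominal mammary glands of Sprague-Dawley rats was measured on 24 Affymetrix arrays. Per the labels' protocols, male and female rats carried subcutaneous osmotic pumps that delivered 17β-estradiol, the main ovarian estrogen, from weaning on postnatal day 21 until postnatal day 33, at 0, 0.1, 1 or 10 µg per kg body weight per day. Total RNA from frozen gland pairs was labelled with biotin and hybridised, per the labels' protocols. Sex and dose make 8 groups of 3 arrays, and the groups were taken from the sample titles. The labels do not say whether each array stands for a separate animal, so p-values measure the spread between these arrays, part of which may be technical.

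The deposited table holds signed log values for 31099 probe sets and 24 arrays, taken here as log2 values. GCOS, the Affymetrix operating software, is named without a role or version per the submitters' processing notes. The methods of summarization, normalization and centring are not given in the sources used here, nor is the log base. The widest range of a probe set within a sex, 7.52 units, rules out log10 but not the natural log, so tests and directions hold for any base while fold changes depend on it. No value was missing and 0 pairs of arrays were identical.

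The values themselves show a centring of each probe set within each sex. In 14299 probe sets the values closest to 0 on either side were equal and opposite within a tolerance of 2e-06, and in 2 of these the pair came from different sexes. This held in 45.3% of probe sets over the female arrays and 41.9% over the male arrays. Subtracting a median over 18 arrays of a sex, of which 12 were analysed here, would give 43.1%. Other arrays were not analysed here. The table therefore keeps no absolute level and no difference in level between the sexes. Differences between doses within a sex, and differences of these between sexes, are kept. The planned comparisons of males with females at 0 and at 10 could not be made, nor could the sex labels be checked. The mean of 4 probe sets for Xist, the transcript that silences an X chromosome, was -0.05 ± 0.15 in females and 0.03 ± 0.13 in males (SD, n = 12 arrays each), and Uty and Eif2s3y on the Y chromosome gave no difference either. Expression and depth relative to background cannot be judged from centred values, and the number of arrays limits the precision. Array medians lay between -0.0175 and 0.0134, so no further normalization was applied.

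Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed. Of the probe sets, 57 Affymetrix controls were left out and 31042 were tested. The platform annotation gave 1 gene for 20826 probe sets (14217 genes), several for 436 and none for 9780. Of those with 1 gene, 20758 matched the reference gene table by gene number, and 0 symbols changed. Genome positions are not given because no build is named for the arrays.

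Each probe set was fitted with 8 group means in limma 3.58.1 under R 4.3.3, with lmFit and eBayes (16 residual degrees of freedom, 2.95 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. The comparisons were each dose against 0 within a sex, and the interaction at each dose, which is the male difference from 0 minus the female difference from 0. Values are log2 differences with standard errors (SE), and folds assume log2 values. The 3 comparisons within a sex share the same 3 control arrays. For correlations between such comparisons, unchanged groups were simulated against shared controls 100 times. The overlap of calls was not simulated.

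Gene lists for mammary cell types, pathways, RNA quality and other tissues were tested with limma's camera at a preset correlation between genes of 0.01, for 25 lists in 9 comparisons, adjusted within each comparison. A gene was represented by its probe set with the largest SD about the mean of its sex, in place of the planned probe set with the highest mean, which centred values do not keep. That SD includes differences between doses, so the choice favours probe sets that change most. Counts of list members and sizes of change may be raised by it. Counts of list members are given over all probe sets tested and adjusted over the list alone. Hepatocyte markers were added as a list of 16 genes after the data were examined, and a further list of 24 was written before the values of those genes were looked at.

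Named genes were chosen by rule. These are the 10 largest rises and the 10 largest falls among probe sets past the threshold with 1 gene whose groups did not overlap (for interactions overlap was allowed), up to 4 members of each list that passed or, where none passed, up to 2 with the smallest p, and always Esr1, Pgr, Prlr, Areg, Greb1 and Csn2. Where fewer than 10 probe sets passed, up to 10 genes with the smallest p were taken as values only. RNA quality was followed as the difference between the 3′ and 5′ control probe sets of beta-actin on each array. The planned difference for Gapdh was also taken, as was one for hexokinase that had not been planned. Only the beta-actin difference was used as a covariate, a choice made after the data were seen.

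The alternatives were a fit of only the groups compared, 1 probe set per gene, an unadjusted p under 0.05 with a fold of 2, array weights, the replicate number as a block, an estimated correlation between genes, and leaving out each array in turn. Those added after seeing the data were array medians set to 0, only the probe sets of larger SD, the mean of a gene's probe sets, covariates for muscle, lymphocyte and hepatocyte markers, a covariate for the beta-actin difference, and leaving out arrays with a wide spread or with hepatocyte transcripts.

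The steps were tested on simulated values drawn independently for each probe set, with its residual SD in the real arrays. The simulation held no correlation between genes and the same spread in every array. Its false calls therefore do not carry over to real arrays that share tissue differences. For 31042 probe sets and the contrast of male 10 against 0, the test called 56.7% of changes of 0.5, 79.1% of changes of 1 and 97.0% of changes of 2 on the log2 scale, with 9 false calls. For the interaction at 10 and the same 31042 probe sets it called 23.9%, 62.7% and 92.4%, with 6 false calls. With 14217 genes in male 10 against 0, camera called the 1 list that had been shifted and 0 of the other 24.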

Results

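The abdominal mammary glands of male and female rats were profiled on postnatal day 33, after infusion of 17β-estradiol from day 21 at 0, 0.1, 1 or 10 µg/kg/day, with 3 arrays in each of the 8 groups and 31042 probe sets tested. The study addressed how the prepubertal gland of each sex responds to exogenous estradiol. Every value below is a log2 difference from the group of the same sex at 0, with its SE and n = 3 arrays per group unless stated, since each probe set had been centred within each sex.

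Several arrays stood apart in markers of other tissues. The mean of 16 hepatocyte markers was 3.40 in female replicate 1 at 0, 2.21 and 3.31 in male replicates 2 and 3 at 0, 1.21 in female replicate 7 at 1 and 1.61 in male replicate 7 at 1. The mean of skeletal muscle markers ranged from -3.28 in female replicate 1 at 0 to 2.05 in female replicate 4 at 0.1. The beta-actin 3′ minus 5′ difference was -0.56, -0.06 and -0.28 in the males at 0 and -0.02, 0.16 and 0.05 in the males at 10. The Gapdh difference was -0.14, -0.07 and -0.03 in the males at 0 and 0.01, -0.06 and -0.02 in the males at 10. For hexokinase it was -0.29, -0.36 and -0.12 in the males at 0 and -0.12, 0.14 and 0.12 in the males at 10. The SD over probe sets was widest in female replicate 4 at 0.1, at 0.485, and in male replicate 1 at 0, at 0.395. Male replicate 1 also had the lowest beta-actin difference of the males at 0. It is the only male control left where the arrays with hepatocyte transcripts are taken out.

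**Figure D1:**
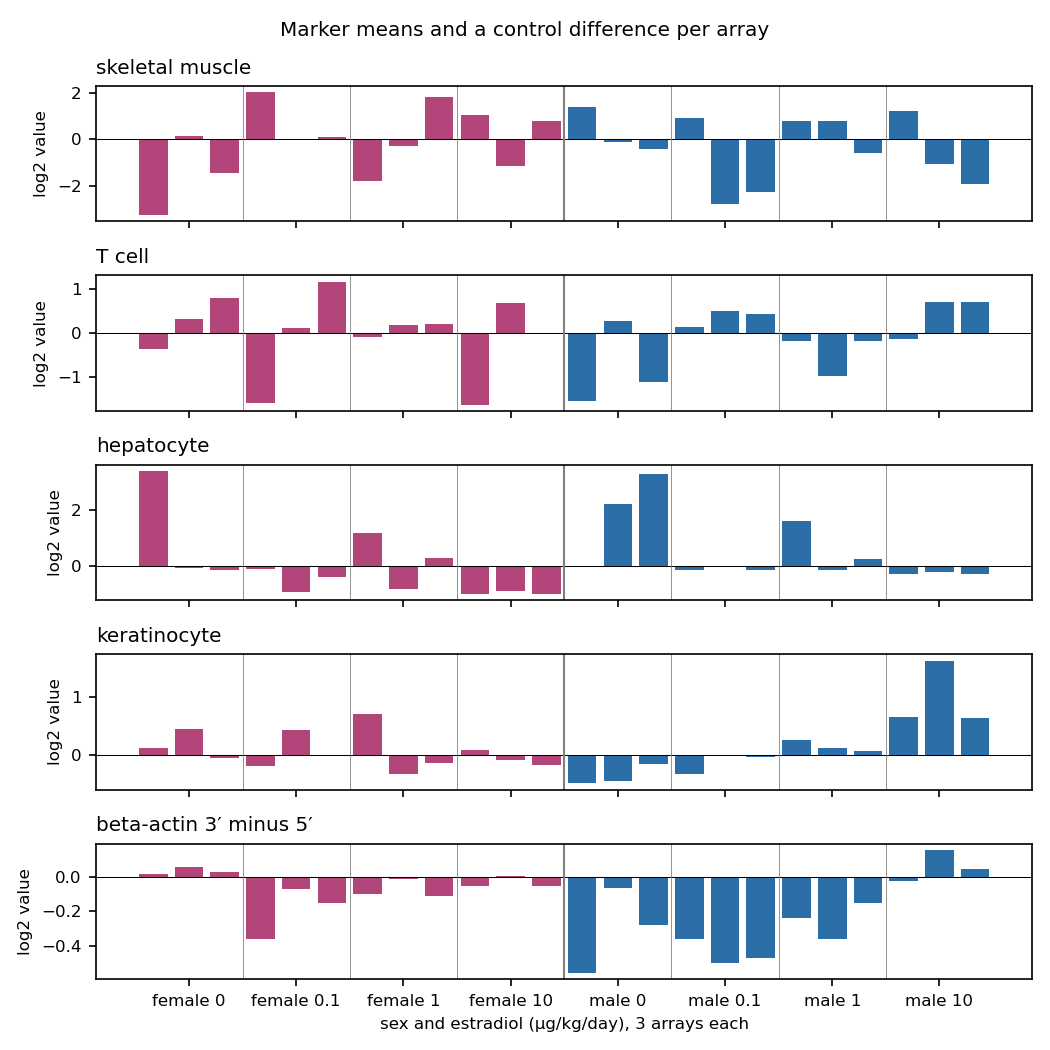
Mean log2 value of skeletal muscle, T cell, hepatocyte and keratinocyte markers and the beta-actin 3′ minus 5′ difference, as a bar for each of the 24 arrays, by sex and estradiol dose in µg/kg/day. Hepatocyte markers reached 3.40 in a female array and 3.31 in a male array at 0, and the beta-actin difference in males was nearest to 0 or above it at 10.

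In females at 10 µg/kg/day, genes of milk secretion rose. Wap, which encodes whey acidic protein of rodent milk, rose by 4.30 ± 0.67 (19.7-fold, 95% confidence interval 7.47 to 51.8, adjusted p = 0.00244). Olah, a thioesterase that releases medium-chain fatty acids in the lactating gland, rose by 2.21 ± 0.38, and the kappa-casein gene Csn3 by 1.89 ± 0.40. Of 20 measured milk protein and secretory genes, 9 rose, 0 fell and 11 did not pass, and 15 rose when adjusted over the list alone. The list was higher than other genes (adjusted p = 6.35e-17, and adjusted p = 0.0262 with an estimated correlation). The beta-casein gene Csn2 gave 2.44 ± 0.77 (adjusted p = 0.119) and did not pass. The luminal epithelial genes Elf5, a transcription factor of alveolar cells (1.80 ± 0.46), Muc1 (1.63 ± 0.33) and Ehf (1.30 ± 0.22) rose, while 19 of the 22 luminal markers did not pass and 5 rose when adjusted over the list alone (adjusted p = 1.13e-06, and adjusted p = 0.417 with an estimated correlation).

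Among targets of the estrogen receptor in females at 10, Greb1 rose by 1.56 ± 0.37 and Pgr, the progesterone receptor, by 1.42 ± 0.33. In all, 3 of the 23 targets rose and 0 fell (4 rose and 1 fell when adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.215). With tissue marker covariates 0 rose and 1 fell, and without the 5 arrays with hepatocyte transcripts 0 passed. Greb1 and Pgr lost the call under both, and in a fit of the 2 groups alone. Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, gave 0.20 ± 0.44 (adjusted p = 0.907). Of 36 cell cycle genes, 0 passed in limma over all probe sets while 21 rose when adjusted over the list alone. Examples are Nusap1 at 0.87 ± 0.23 (adjusted p = 0.0616) and Ccnb2 at 0.69 ± 0.19 (adjusted p = 0.0684). The list was higher than other genes (adjusted p = 3.79e-12, and adjusted p = 0.413 with an estimated correlation). With tissue marker covariates 9 of the 36 rose over all probe sets. The mean of the list was 0.72 in replicate 10 at 10, which also stood apart in T cell markers (-1.62), and 0.06 and -0.03 in replicates 11 and 12, against -0.01, -0.16 and -0.37 in the controls.

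Genes of fat cells, sterol synthesis and mast cells fell in females at 10. Of 21 white adipocyte markers 13 fell, 0 rose and 8 did not pass (14 fell when adjusted over the list alone), among them Agpat2, an acyltransferase of triglyceride synthesis (-1.64 ± 0.24), and Dgat2, which catalyses the last step of that pathway (-1.14 ± 0.21). The list was lower at adjusted p = 1.51e-17, and adjusted p = 0.0589 with an estimated correlation. Adrb3, the beta-3 adrenergic receptor of adipocytes, had a difference of -1.84 ± 0.20. Of 19 cholesterol synthesis genes 7 fell, 0 rose and 12 did not pass, and 12 fell when adjusted over the list alone. Insig1, a sterol-regulated brake on the pathway, was at -1.39 ± 0.25 and the enzyme Nsdhl at -0.94 ± 0.17 (list adjusted p = 6.94e-13, and adjusted p = 0.0488 with an estimated correlation). Of 17 mast cell and eosinophil markers 6 fell and 0 rose, and 10 fell when adjusted over the list alone, including Hdc, the enzyme that makes histamine (-1.12 ± 0.16), and Fcer1a of the IgE receptor (-1.21 ± 0.26). That list was lower at adjusted p = 2.41e-07, and adjusted p = 0.047 with an estimated correlation. Alb, which encodes serum albumin of the liver, had the largest fall of the named genes (-3.89 ± 0.68), while hepatocyte markers averaged 3.40, -0.06 and -0.11 in the control arrays and -0.98, -0.89 and -0.98 in the arrays at 10. Without the 5 arrays with hepatocyte transcripts, which leaves 2 control arrays, Alb still passed the threshold. Skeletal muscle markers had a median difference of 1.59, with 0 of 28 past the threshold in limma and 0 when adjusted over the list alone (adjusted p = 9.89e-06, and adjusted p = 0.577 with an estimated correlation). B and T cell markers had medians of -0.46 and -0.63, with 0 of 18 and 0 of 17 past the threshold and 0 when adjusted over the list alone (adjusted p = 0.0426 and 0.0488, and adjusted p = 0.741 for both with an estimated correlation). In all, limma called 252 probe sets higher and 325 lower in females at 10 against 0 (167 and 207 genes), and 4040 had an unadjusted p under 0.05. The count of 577 was 127 in a fit of the 2 groups alone, 90 without the 5 arrays with hepatocyte transcripts (49 higher and 41 lower, with 2 control arrays left), 1039 with tissue marker covariates (547 higher and 492 lower), 963 without the 2 widest arrays and 1218 with array weights. It was 164, 260 and 259 without replicates 1, 2 and 3 at 0, and 158 and 231 without replicates 10 and 11 at 10. Of 45 named genes past the threshold 15 stayed past it whichever array was left out, among them Wap, Olah, Ehf, Adrb3, Agpat2, Insig1, Nsdhl, Hdc and Alb, while Csn3, Elf5, Muc1, Greb1, Pgr, Dgat2 and Fcer1a did not. Under every alternative setting 8 of the 45 stayed past it, and 7 did so without any array as well, among them Wap, Olah, Adrb3, Agpat2 and Hdc. Ehf and Alb lost the call in a fit of the 2 groups alone, and Ehf, Insig1 and Nsdhl without the 5 arrays with hepatocyte transcripts. Without those 5 arrays 6 milk genes and 0 luminal markers rose, and 1 white adipocyte marker, 2 cholesterol synthesis genes and 1 mast cell marker fell.

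In females at 0.1 and 1 µg/kg/day no gene passed the threshold in limma. At 0.1 the smallest adjusted p was 0.0652. It was shared by genes of fat storage such as Fabp4, a fatty acid binding protein of adipocytes (-0.48 ± 0.08), Plin1, which coats their lipid droplets (-0.92 ± 0.17), and Adrb3 (-1.11 ± 0.20). Of 21 white adipocyte markers 0 passed over all probe sets and 16 fell when adjusted over the list alone, with a list median of -0.67 (adjusted p = 3.98e-20, and adjusted p = 0.151 with an estimated correlation). Skeletal muscle markers had a median of 2.12 in the same comparison, with 0 of 28 past the threshold and 0 when adjusted over the list alone (adjusted p = 1.26e-10, and adjusted p = 0.591 with an estimated correlation). At 1 the smallest adjusted p was 1. Wap gave 1.88 ± 0.67 and Cyp51 of sterol synthesis -0.46 ± 0.10. The cholesterol synthesis list had a median of -0.23, with 0 of 19 past the threshold and 2 lower when adjusted over the list alone (adjusted p = 1.73e-12, and adjusted p = 0.0915 with an estimated correlation). In the same comparison skeletal muscle markers had a median of 1.20 (adjusted p = 2.52e-10, and adjusted p = 0.336 with an estimated correlation), macrophage markers 0.18 (adjusted p = 1.44e-06, and adjusted p = 0.299 with an estimated correlation) and white adipocyte markers -0.27 (adjusted p = 1.7e-06, and adjusted p = 0.299 with an estimated correlation). None of these 28, 18 and 21 markers passed, over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 there were 3083 probe sets at 0.1 and 847 at 1, where chance gives 1552. The count of 0 at 0.1 became 204 without female replicate 4 at 0.1, 21 without replicate 5 and 2 without replicate 6, and 1738 with array weights. The weights of replicates 4, 5 and 6 were 0.16, 3.48 and 0.45, so the weighted mean at 0.1 rested mostly on replicate 5. The count at 1 was 0 with array weights and 0 whichever array was left out, and 10 at an unadjusted p under 0.05 with a fold of 2.

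In males at 10 µg/kg/day, Areg rose by 5.36 ± 0.44 (40.9-fold, 95% confidence interval 21.5 to 77.8, adjusted p = 1.03e-06), Greb1 by 3.26 ± 0.37 and Pgr by 2.93 ± 0.33. Prlr, the prolactin receptor, rose by 1.19 ± 0.26, while the estrogen receptor gene Esr1 fell by 0.64 ± 0.18 and Igf1, a growth factor, fell by 1.35 ± 0.19. Of 23 targets 7 rose and 3 fell (9 and 5 when adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.118). Clca1 rose by 5.41 ± 0.95, the retinol transporter gene Stra6 by 3.57 ± 0.47, with 4 of its 5 probe sets of the same sign, and Tnc, which encodes the matrix protein tenascin-C, by 3.10 ± 0.38. Egfr, the receptor of amphiregulin, rose by 1.33 ± 0.14. Among milk genes Csn2 rose by 3.41 ± 0.77 and Csn3 by 1.75 ± 0.40. Of these 20 genes 4 rose and 1 fell (5 and 2 when adjusted over the list alone), and the list did not pass (adjusted p = 0.0619). With tissue marker covariates 2 rose and 1 fell, and with the beta-actin covariate 0 passed.

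Some markers of epithelial and skin cells rose in males at 10. Of 22 luminal markers 9 rose, 0 fell and 13 did not pass, and 16 rose when adjusted over the list alone. Gata3, a luminal transcription factor, rose by 1.19 ± 0.32 (list adjusted p = 3.31e-06, and adjusted p = 0.438 with an estimated correlation). Of 16 basal markers 6 rose and 1 fell (7 and 1 when adjusted over the list alone), with the basal keratin Krt14 at 2.25 ± 0.40 and the basal transcription factor Tp63 at 1.76 ± 0.36, for which 1 of 2 probe sets had this sign (list adjusted p = 0.00885, and adjusted p = 0.544 with an estimated correlation). Of 15 keratinocyte markers 10 rose, both over all probe sets and adjusted over the list alone, and 0 fell. They include Krt71, a keratin of the hair follicle sheath (3.94 ± 1.16), and Lgals7, galectin-7 of stratified epithelia (2.28 ± 0.33), at adjusted p = 3.31e-06, and adjusted p = 0.219 with an estimated correlation. The keratinocyte mean was 0.66, 1.63 and 0.64 in the male arrays at 10, the highest in replicate 11. Tchh, the hair follicle protein trichohyalin, rose by 4.92 ± 1.51. B cell markers had a median of 1.11, with 0 of 18 past the threshold and 0 when adjusted over the list alone (adjusted p = 0.000161, and adjusted p = 0.517 with an estimated correlation). T cell markers had a median of 1.35, with 1 of 17 higher and 0 when adjusted over the list alone (adjusted p = 0.00264, and adjusted p = 0.544 with an estimated correlation). With tissue marker covariates 1 of 22 luminal, 5 of 16 basal and 5 of 15 keratinocyte markers were higher, and Gata3, Krt71 and Tchh did not pass. With the beta-actin covariate these counts were 1, 1 and 2. The luminal median was 0.75, and 0.63 and 0.36 with these covariates, the basal median 0.28, and 0.095 and 0.25, and the keratinocyte median 1.32, and 1.18 and 1.09. Gata3, Krt71 and Tchh also lost the call without the 2 widest arrays and without some single arrays. Krt14, Tp63 and Lgals7 kept it in both cases.

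**Figure D2:**
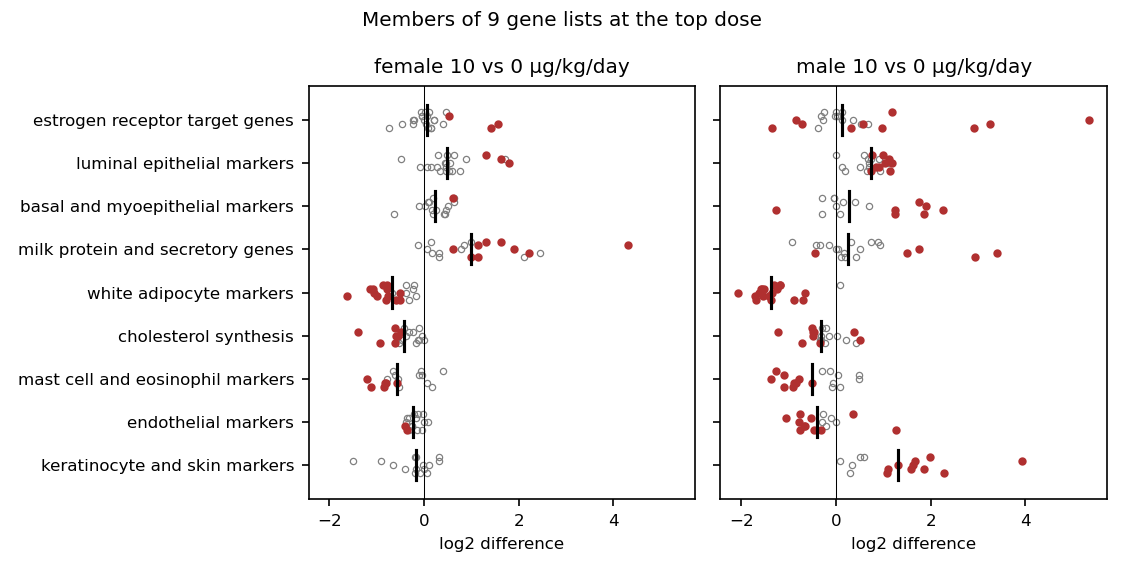
Log2 difference at 10 against 0 µg/kg/day in females and males for each measured member of 9 gene lists, with filled points past an adjusted p of 0.05, open points not past it, and a bar at each list median. White adipocyte markers had medians of -0.68 in females and -1.36 in males, and keratinocyte markers -0.17 and 1.32.

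Genes of adipocytes, endothelium, mast cells and steroid handling fell in males at 10. Of 21 white adipocyte markers 19 fell, 0 rose and 2 did not pass, and 20 fell when adjusted over the list alone (adjusted p = 1.99e-16, and adjusted p = 0.219 with an estimated correlation). Gpd1, which makes the glycerol backbone of fats, was at -2.07 ± 0.21, the glycerol channel gene Aqp7 at -1.70 ± 0.19 and Cebpa, a transcription factor of fat cells, at -1.62 ± 0.23. Of 16 endothelial markers 9 fell and 2 rose, over all probe sets and adjusted over the list alone alike, with Nos3, the endothelial nitric oxide synthase, at -1.05 ± 0.23 and Prox1, a lymphatic regulator, at 1.26 ± 0.26 (list adjusted p = 0.000496, and adjusted p = 0.342 with an estimated correlation). Of 17 mast cell and eosinophil markers 9 fell and 0 rose (10 fell when adjusted over the list alone), including Hdc at -1.11 ± 0.16 and the tryptase gene Tpsab1 at -1.37 ± 0.22 (adjusted p = 0.000517, and adjusted p = 0.219 with an estimated correlation). Of 16 hormone receptor and steroid metabolism genes 10 fell and 1 rose, over all probe sets and adjusted over the list alone alike. Sult1e1, which inactivates estrogens by sulfation, was at -2.08 ± 0.33 and Ghr, the growth hormone receptor, at -1.82 ± 0.30 (adjusted p = 0.000161, and adjusted p = 0.219 with an estimated correlation). Fatty acid oxidation genes fell in 8 of 18 cases, over all probe sets and adjusted over the list alone alike, with Etfdh at -0.86 ± 0.18 (adjusted p = 0.00028, and adjusted p = 0.41 with an estimated correlation). With tissue marker covariates 18 white adipocyte, 8 endothelial, 6 mast cell, 7 hormone receptor and 3 fatty acid oxidation genes fell, the last with a median of -0.21 against -0.46. With the beta-actin covariate these counts were 13, 3, 4, 2 and 1. Alb fell by 3.50 ± 0.68, with hepatocyte markers averaging -0.02, 2.21 and 3.31 in the controls and -0.28, -0.20 and -0.28 in the arrays at 10.

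Limma called 2425 probe sets higher and 2994 lower in males at 10 against 0 (1473 and 2024 genes), of which 354 and 392 changed at least 2-fold, and 9979 had an unadjusted p under 0.05. With the beta-actin 3′ minus 5′ difference as a covariate the count of 5419 was 757, with tissue marker covariates 2709, and with array weights 8955. Without the 5 arrays with hepatocyte transcripts it was 3302, a contrast with 1 control array, replicate 1, which is assumed to vary like the other groups. More probe sets were higher than lower at an unadjusted p under 0.05 with a fold of 2 (508 and 432) and with array weights (4639 and 4316). The count was 2685 without male replicate 1 at 0, 2919 without replicate 11 at 10 and 3497 without replicate 12 at 10. Of 93 named genes past the threshold, 59 stayed past it whichever array was left out, and 27 also under every alternative setting. Areg, Clca1, Stra6, Greb1, Pgr, Tnc, Egfr, Gpd1, Aqp7, Cebpa, Hdc and Alb are among the 27, while Csn2, Csn3, Krt14, Tp63, Krt71, Tchh, Gata3, Nos3, Prox1, Tpsab1, Etfdh, Sult1e1, Ghr, Prlr and Esr1 did not pass with the beta-actin covariate.

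In males at 1 µg/kg/day, Areg rose by 3.19 ± 0.44 (9.09-fold, 95% confidence interval 4.79 to 17.3, adjusted p = 0.00117), Pgr by 1.75 ± 0.33, Prlr by 1.55 ± 0.26 and Wnt4, a signal in duct side-branching, by 1.29 ± 0.22. Stra6 rose by 2.71 ± 0.47, Tnc by 2.32 ± 0.38, the water channel gene Aqp5 by 2.15 ± 0.30 and Egr2, a transcription factor, by 1.85 ± 0.22. Of 23 estrogen receptor targets 4 rose and 0 fell (6 and 3 when adjusted over the list alone, list adjusted p = 0.0794). Greb1 gave 1.26 ± 0.37 (adjusted p = 0.063), Csn2 2.46 ± 0.77 (adjusted p = 0.0794) and Esr1 -0.51 ± 0.18 (adjusted p = 0.116). Of 22 luminal markers 12 rose, 0 fell and 10 did not pass, and 19 rose when adjusted over the list alone. The adhesion gene Epcam rose by 1.36 ± 0.32 (adjusted p = 1.91e-14, and adjusted p = 0.186 with an estimated correlation). Of 16 basal markers 6 rose and 1 fell (13 and 1 when adjusted over the list alone), with Krt5 at 1.5 ± 0.40 (adjusted p = 2.56e-08, and adjusted p = 0.203 with an estimated correlation). Of 15 keratinocyte and skin markers 3 rose, 0 fell and 12 did not pass (4 rose when adjusted over the list alone), namely Dsp (1.72 ± 0.40), Lgals7 (1.59 ± 0.33) and Perp (1.51 ± 0.42), at adjusted p = 0.0265, and adjusted p = 0.576 with an estimated correlation. Of 21 white adipocyte markers 13 fell, 0 rose and 8 did not pass, and 19 fell when adjusted over the list alone. Pparg, the main regulator of fat cell formation, was at -1.06 ± 0.18 and Aqp7 at -1.13 ± 0.19 (adjusted p = 1.91e-14, and adjusted p = 0.186 with an estimated correlation). B cell markers had a median of 0.49, with 0 of 18 past the threshold and 0 when adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.682 with an estimated correlation). Hepatocyte markers were also raised in the control replicates 2 and 3, at 2.21 and 3.31, and in replicate 7 at 1, at 1.61.

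Limma called 475 probe sets higher and 652 lower in males at 1 against 0 (312 and 466 genes), and 5735 had an unadjusted p under 0.05. The count of 1127 was 468 without the 2 widest arrays, 1691 with tissue marker covariates (854 higher and 837 lower) and 2375 with array weights. At an unadjusted p under 0.05 with a fold of 2 there were 232 higher and 70 lower. Without the 5 arrays with hepatocyte transcripts it was 209 (152 higher, 57 lower), with 1 control array, replicate 1, left, and Pgr, Tnc, Pparg and Aqp7 did not pass. The count was 165 and 454 without male replicates 1 and 2 at 0, and 313, 554 and 196 without replicates 7, 8 and 9 at 1. Of 54 named genes past the threshold 17 stayed past it whichever array was left out, among them Areg, Pgr, Prlr, Wnt4, Stra6, Tnc, Aqp5, Egr2, Pparg and Aqp7, while Epcam, Krt5, Dsp, Lgals7 and Perp did not. Under every alternative setting 8 stayed past it, among them Areg, Stra6, Aqp5, Egr2 and Prlr. Without the 2 widest arrays 2 luminal and 2 basal markers rose and 8 white adipocyte markers fell, and without the 5 arrays with hepatocyte transcripts these counts were 3, 1 and 0.

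In males at 0.1 µg/kg/day no gene passed in limma, where the smallest adjusted p was 0.102 and 3703 probe sets had an unadjusted p under 0.05. Areg gave 1.32 ± 0.44 (adjusted p = 0.343), Pgr 0.56 ± 0.33 and Prlr 0.73 ± 0.26. Of 22 luminal markers 0 passed over all probe sets and 11 rose when adjusted over the list alone, with a list median of 0.78 (adjusted p = 1.62e-10, and adjusted p = 0.354 with an estimated correlation). Epcam gave 0.95 ± 0.32 (adjusted p = 0.35). White adipocyte markers had a median of -0.44, with 0 of 21 past the threshold and 5 lower when adjusted over the list alone (adjusted p = 2.59e-08, and adjusted p = 0.354 with an estimated correlation). T cell markers had a median of 1.26, with 0 of 17 past the threshold and 0 when adjusted over the list alone (adjusted p = 5.32e-06, and adjusted p = 0.458 with an estimated correlation). B cell markers had a median of 0.84 (adjusted p = 6.65e-06, and adjusted p = 0.458 with an estimated correlation) and skeletal muscle markers -1.59 (adjusted p = 1.18e-05, and adjusted p = 0.571 with an estimated correlation), with 0 of 18 and 0 of 28 past the threshold or when adjusted over the list alone. The count of 0 was 982 with the beta-actin covariate, 180 with array weights and 1 without male replicate 3 at 0. It was 20 without the 5 arrays with hepatocyte transcripts, which leaves 1 male control array.

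**Figure D3:**
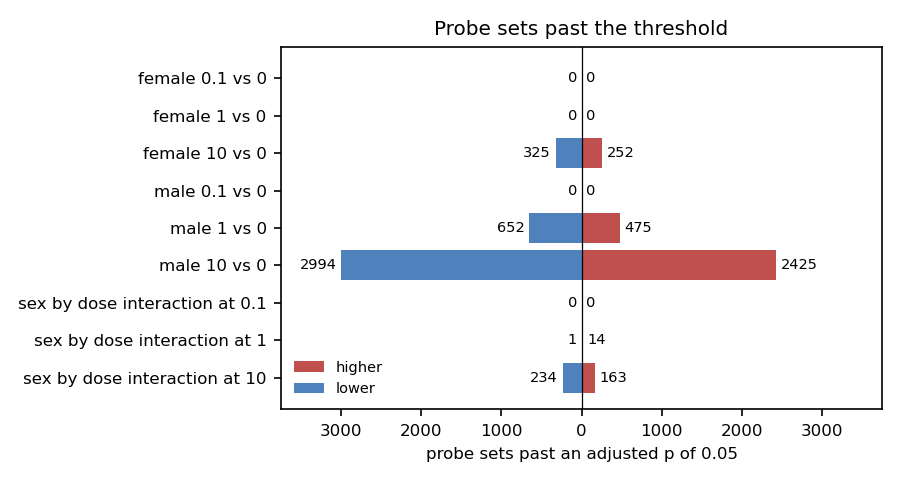
Probe sets past an adjusted p of 0.05 in each of the 9 comparisons, with bars to the right for higher and to the left for lower values. Males at 10 µg/kg/day had 2425 higher and 2994 lower, females at 10 had 252 and 325, and no probe set passed at 0.1 in either sex.

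The response at 10 µg/kg/day differed between the sexes for 397 probe sets, tested as an interaction. Greater and lower are meant with the sign, so a lower male response can be a larger fall in males. Areg responded more in males by 5.15 ± 0.63 (adjusted p = 0.000652, n = 3 arrays in each of 4 groups), Tnc by 3.11 ± 0.54, Stra6 by 2.83 ± 0.66, Egr2 by 2.35 ± 0.30 and Lgals7 by 2.21 ± 0.46. The male response was lower than the female response for Sult1e1 (-2.42 ± 0.47), for Deptor, an inhibitor of the growth kinase mTOR (-2.0 ± 0.25), for the phosphatase gene Dusp1 (-1.74 ± 0.31), for the milk peroxidase gene Lpo (-1.56 ± 0.27) and for Ehf (-1.30 ± 0.31). Sult1e1 and Dusp1 stood at -2.08 and -1.945 in males at 10 against 0, so their lower male response was a fall in males. Pgr at 1.5 ± 0.46 (adjusted p = 0.0999) and Greb1 at 1.70 ± 0.52 (adjusted p = 0.102) did not pass. Of 20 milk genes 3 had a lower male response and 0 a greater one (6 and 0 when adjusted over the list alone, list adjusted p = 0.000352, and adjusted p = 0.648 with an estimated correlation). Of 15 keratinocyte markers 1 had a greater male response, and 11 when adjusted over the list alone (adjusted p = 2.95e-08, and adjusted p = 0.354 with an estimated correlation). White adipocyte markers had a median of -0.54, with 0 of 21 past the threshold in limma and 7 lower when adjusted over the list alone (adjusted p = 5.39e-05, and adjusted p = 0.648 with an estimated correlation). Skeletal muscle markers had a median of -2.50, with 0 of 28 past the threshold or when adjusted over the list alone (adjusted p = 0.000267, and adjusted p = 0.777 with an estimated correlation). B and T cell markers had medians of 1.43 and 1.91, with 0 of 18 and 0 of 17 past the threshold or when adjusted over the list alone (adjusted p = 7.26e-07 and 4.01e-05, and adjusted p = 0.648 and 0.662 with an estimated correlation).

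**Figure D4:**
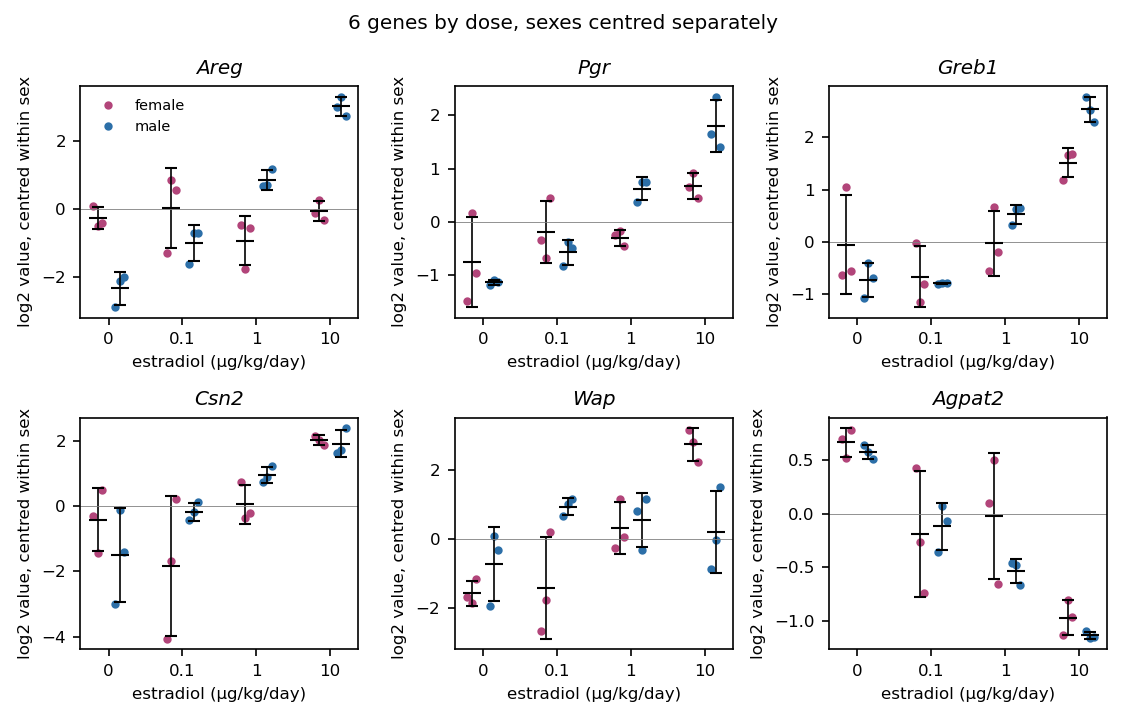
Log2 values, centred within each sex, of Areg, Pgr, Greb1, Csn2, Wap and Agpat2 by estradiol dose in µg/kg/day, with a point for each array and lines at the mean ± SD of 3 arrays. Levels cannot be compared between sexes, and the change from 0 to 10 in Areg was 5.36 in males and 0.20 in females.

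The interaction at 10 comprised 163 probe sets with a greater and 234 with a lower male response, taken with its sign (85 and 199 genes). An unadjusted p under 0.05 was reached by 5908. Of these 397, 79 with a greater and 52 with a lower male response differed at least 2-fold. At an unadjusted p under 0.05 with a fold of 2 there were 465 and 185, so the balance of directions depends on the threshold. At the adjusted threshold it also turned with the beta-actin covariate (14 and 9) and with array weights (1853 and 1638). It was 42 and 23 without female replicate 3 at 0, and 102 and 94 without male replicate 3 at 0. The other settings at that threshold kept more probe sets with a lower male response. The count of 397 was 23 with the beta-actin covariate, and 3491 with array weights. Where the count stayed similar, its members could still change. Among the 397 were 166 of the 335 called with tissue marker covariates and 247 of the 443 called with the replicate block. In a fit of only the groups compared it was 286 of 514, and with array medians set to 0 it was 390 of 398. The count was 112 and 65 without female replicates 2 and 3 at 0, and 69 and 88 without female replicates 10 and 12 at 10. Without male replicates 1 and 3 at 0 it was 76 and 196, and without male replicates 10, 11 and 12 at 10 it was 206, 172 and 147. Of 28 named genes past the threshold 9 stayed past it whichever array was left out, among them Areg, Deptor, Egr2, Tnc, Dusp1 and Lpo. Areg and Deptor also stayed past it under every setting tried, while Stra6, Sult1e1, Lgals7 and Ehf lost the call without some arrays. Tnc, Dusp1 and Lpo lost it with the beta-actin covariate.

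At 1 µg/kg/day the male response was again greater for Areg, by 3.85 ± 0.63 (adjusted p = 0.0307), Egr2 by 2.06 ± 0.30, Pcdh10, a cell adhesion gene, by 1.99 ± 0.33, Serpinb9 by 1.52 ± 0.26 and Spon1 by 1.12 ± 0.20. For Slc9a9, an endosomal sodium-proton exchanger gene, the male response was lower with its sign, at -0.95 ± 0.16. In all 14 probe sets had a greater and 1 a lower male response in limma, and 3059 had an unadjusted p under 0.05. The count of 15 was 0 in a fit of the 4 groups alone, 0 with the beta-actin covariate and 83 with array weights. It was 0 without female replicates 2 or 3 at 0, female replicates 8 or 9 at 1, male replicate 1 at 0 or male replicates 7, 8 or 9 at 1, 7 without female replicate 7 at 1 and 51 without male replicate 3 at 0. At 0.1 limma called 0 probe sets, with a smallest adjusted p of 0.621 and 2266 at an unadjusted p under 0.05. Adamts8, a metalloprotease gene, at -1.18 ± 0.26 and Sfrp1, a Wnt antagonist gene, at 0.70 ± 0.17 were among the smallest p. Skeletal muscle markers had a median of -3.58 there, with 0 of 28 past the threshold and 3 lower when adjusted over the list alone (adjusted p = 4.73e-16, and adjusted p = 0.546 with an estimated correlation).

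Calls at 10 µg/kg/day overlapped between the sexes, which share no arrays, although control arrays of both sexes held hepatocyte transcripts (3.40 in a female array, 2.21 and 3.31 in male arrays). The female count was 90 without the 5 such arrays, and the overlap was not computed without them. Of 577 probe sets called in females 386 were also called in males, 127 higher and 246 lower in both and 13 in opposite directions, where independent lists would give 19.7 and 31.3 (Fisher's exact test, two-sided, p = 1.28e-155, over probe sets that are not independent). The males had the same sign in 505 of the 577 (87.5%), and the females in 71.6% of the 5419 male calls. Over all probe sets the differences of the sexes correlated at r = 0.20. Greb1, Pgr, Zbtb40, Csn3, Agpat2, Hdc and Alb were called in both sexes. Between males at 1 and at 10, which share their controls, 364 probe sets were higher in both and 622 lower, with 0 opposite, where independent lists would give 37.1 and 62.9. Across probe sets their log2 differences correlated at r = 0.83 with a covariance of 0.0946. Simulated unchanged groups with shared controls gave a mean r of 0.44 (central 95% of 100 draws from -0.25 to 0.88) and a mean covariance of 0.0191. The r of 0.83 lay within that range, so by itself it cannot be told apart from an effect of shared controls. The counts for independent lists do not allow for shared controls, and the overlap of calls was not simulated. Part of the overlap may come from the shared controls, and how much was not tested.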

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

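The results in this part drew attention because the response to estradiol differed between males and females in an interaction test. Both tests of the higher male count, by tissue covariates and by the beta-actin covariate, were chosen only after the result was seen. At 10 µg/kg/day 397 probe sets differed. Areg (5.15), Tnc (3.11), Stra6 (2.83), Egr2 (2.35), Lgals7 (2.21), Tmem35a (2.11), 6330403K07Rikl (2.07), Gosr1 (2.04), Gpr37 (1.95) and Sfn (1.88) had the greatest excess of the male response. Sult1e1 (-2.42), Pdk4 (-2.05), Deptor (-2.0), Fam13a (-1.84), Dusp1 (-1.74), Ankrd34b (-1.67), Angpt1 (-1.59), Nnat (-1.56), Lpo (-1.56) and Dpep1 (-1.56) had the male difference furthest below the female one, which can be a larger fall in males. At 1 µg/kg/day 15 probe sets differed, among them Areg (3.85), Egr2 (2.06), Pcdh10 (1.99), Serpinb9 (1.52), Spon1 (1.12) and Slc9a9 (-0.95).

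Gene lists also differed between the sexes in limma's camera at the preset correlation, and none of these differences passed with an estimated correlation. At 10 the list medians were 1.91 for T cells, 1.43 for B cells, 1.29 for keratinocytes, 0.28 for interferon-stimulated genes, 0.23 for cholesterol synthesis, -0.44 for hormone receptors and steroid metabolism, -0.46 for fatty acid oxidation, -0.54 for white adipocytes, -0.64 for milk genes and -2.50 for skeletal muscle. At 1 they were 1.12 for luminal and 0.70 for basal markers, 0.27 for androgen-responsive genes, 0.23 for the cell cycle, 0.18 for keratinocytes, 0.16 for estrogen receptor targets, -0.23 for fatty acid oxidation, -0.31 for hormone receptors, -0.31 for endothelium, -0.32 for macrophages, -0.51 for white adipocytes and -1.05 for skeletal muscle. At 0.1 they were 1.54 for T cells, 1.13 for B cells, 0.68 for milk genes, 0.62 for luminal and 0.44 for basal markers, 0.28 for fatty acid synthesis, 0.25 for white adipocytes, 0.17 for interferon-stimulated genes, -0.12 for fibroblasts and matrix, -0.26 for the cell cycle and -3.58 for skeletal muscle.

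Regrouping the arrays by sex within the doses tested the interaction counts, with 100 of the 200 possible splits drawn. At 10, 1 of 100 splits, the real one, gave as many as 397 probe sets and the highest other gave 12. That share argues against a chance split of these arrays as the source of the count. It does not address array differences that follow sex and dose, and the count was 23 with the beta-actin covariate. At 1, 7 of 100 gave as many as 15 and the highest other gave 106, so chance is not excluded. At 0.1 the real count was 0, so 100 of 100 gave as many, and the highest other gave 503. Which arrays formed that split was not examined, so its source stays open. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. In females at 10 and in males at 1 and at 10, 1 of 10 splits gave as many as the real 577, 1127 and 5419, and the highest other gave 0 in each. In females at 0.1 and at 1 and in males at 0.1, all 10 of 10 gave as many as the real 0, and the highest others gave 2, 2 and 34.

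At 10 µg/kg/day limma called 9.39 times as many probe sets in males as in females. The ratio was 4.13 without the 2 widest arrays. It lay above 9.39 without the 5 arrays with hepatocyte transcripts, a contrast with too few male controls to weigh. Muscle, lymphocyte and hepatocyte RNA as the whole cause is argued against, since with these marker scores as covariates the ratio was 2.61. RNA quality, tested by beta-actin and not by Gapdh or hexokinase, stays open, since with the beta-actin covariate the ratio was 0.97. Male differences then had a median 0.74 of their former size and SE 1.33 times as large (median size 0.52 before and 0.37 after, SE 0.13 and 0.16), and the actin difference of each male array at 10 lay above that of each male control, so the covariate may have taken up part of the dose effect. A greater male sensitivity to estradiol, and other differences between the sexes, remain open and untested.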

How the results depend on the processing

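The order below is females at 0.1, 1 and 10, males at 0.1, 1 and 10, and the interactions at 0.1, 1 and 10, where the counts were 0, 0, 577, 0, 1127, 5419, 0, 15 and 397. A fit of only the groups compared gave 127 for females at 10 and 0 for the interaction at 1. With 1 probe set per gene the counts were 2 for females at 0.1, 375 for females at 10, 3285 for males at 10 and 5 for the interaction at 1. An unadjusted p under 0.05 with a fold of 2 gave 78, 10, 249, 143, 302, 940, 152, 285 and 650. Array weights gave 1738 and 1218 for females at 0.1 and 10, 180, 2375 and 8955 for males, and 4, 83 and 3491 for the interactions, with weights from 0.16 (female replicate 4 at 0.1) to 3.48 (female replicate 5 at 0.1). A replicate block gave 27 for the interaction at 1, although not every pair of same-numbered samples correlated, so the numbers were not taken as pairs (r from -0.48 to 0.59 and over 0.1 in 5 of 12, which are all 3 at 0.1 and 2 of 3 at 10, and 4 of 12 matched best with their own number). With this block named genes such as Ehf, Pdk4, Oxtr and Xdh lost the call in the interaction at 10. Chosen after seeing the data, tissue marker covariates gave 5 and 1039 for females at 0.1 and 10, 1691 and 2709 for males at 1 and 10, and 22 for the interaction at 0.1. The beta-actin covariate gave 982 and 757 for males at 0.1 and 10, and 0 and 23 for the interactions at 1 and 10. Leaving out the 2 widest arrays gave 162 and 963 for females at 0.1 and 10 and 468 for males at 1. Leaving out the 5 arrays with hepatocyte transcripts gave 1 and 90 for females at 0.1 and 10 and 20, 209 and 3302 for males, whose controls were then 1 array, replicate 1. Array medians set to 0 and the probe sets of larger SD moved no count by over 1.5 times. Leaving out single arrays gave, for females at 0.1, 204, 21 and 2 without replicates 4, 5 and 6 at 0.1. For females at 10 it gave 164, 260 and 259 without replicates 1, 2 and 3 at 0, and 158, 231 and 552 without replicates 10, 11 and 12 at 10. Males at 0.1 had 1 without replicate 3 at 0. Males at 1 had 165, 454 and 1205 without replicates 1, 2 and 3 at 0, and 313, 554 and 196 without replicates 7, 8 and 9 at 1. Males at 10 had 2685 and 5239 without replicates 1 and 2 at 0, and 2919 and 3497 without replicates 11 and 12 at 10. The interaction at 1 was 0 without female replicates 2, 3, 8 or 9 or male replicates 1, 7, 8 or 9, 7 without female replicate 7 and 51 without male replicate 3. The interaction at 10 was 575, 112, 65, 69 and 88 without female replicates 1, 2, 3, 10 and 12, and 76, 196, 206, 172 and 147 without male replicates 1, 3, 10, 11 and 12. Of the list tests 99 passed, 3 with an estimated correlation, and 83 to 109 under the other settings. Signs reversed for 30 values of named genes, none past the threshold in either fit, and the cause was not tested. With array weights these were Pgr (-0.049), Prlr (0.28) and Greb1 (-0.27) in females at 0.1, 0.1 and 1, and Pgr in the interaction at 0.1 (0.68). With tissue covariates they were Prlr in females at 0.1 (0.24), Greb1 in females at 1 (-0.19) and Csn2 in the interaction at 10 (-0.93). With the actin covariate they were Prlr in females at 0.1 (0.17) and Csn2 in the interaction at 10 (-1.17). Without the 2 widest arrays they were Prlr in females at 0.1 (0.26) and Esr1 in the interaction at 0.1 (0.061). Without the 5 hepatocyte arrays they were Greb1 in females at 1 (-0.0046) and males at 0.1 (0.28), and Pgr in the interaction at 0.1 (0.41). Without single arrays at 0 they were, for female replicate 1, Greb1 in females at 1 (-0.27) and Pgr in the interaction at 0.1 (0.36); for female replicate 2, Csn2 in females at 1 (-0.043) and Greb1 in the interaction at 0.1 (-0.0058); for female replicate 3, Prlr in females at 0.1 (0.02), Greb1 in females at 1 (-0.23), and Esr1 (0.0074) and Pgr (0.09) in the interaction at 0.1. For male replicates 1 and 2 at 0 they were Esr1 in the interaction at 0.1 (0.15), Greb1 in males at 0.1 (0.088) and Pgr in the interaction at 0.1 (0.02). At other doses they were Prlr (0.26) and Areg (-0.11) in females at 0.1 without female replicates 4 and 5, Greb1 in females at 1 without female replicate 8 (-0.32), and Pgr in the interaction at 0.1 without female replicate 6 (0.31) or male replicate 4 (0.13). The same values without other arrays ranged as far as 0.97 for Areg in females at 0.1 (female replicate 4 at 0.1 left out), 0.57 for Greb1 (female replicate 2 at 0) and 0.93 for Csn2 (female replicate 3 at 0) in females at 1, -0.24 for Greb1 in males at 0.1 (male replicate 1 at 0), and, in the interaction at 0.1, -0.25 for Esr1 (male replicate 2 at 0), -0.47 for Pgr (female replicate 2 at 0) and 0.86 for Greb1 (female replicate 4 at 0.1). Not run, because values centred per probe set hold no level, were the pseudocount or floor, quantile normalization, the filter on low values and both comparisons of males with females.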

Other observations

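Both tests of hepatocyte transcripts and the adipocyte test by endothelial markers were chosen only after the result was seen. Stromal and signalling genes moved both ways in males at 10 µg/kg/day. Of 29 fibroblast and matrix genes 7 rose and 10 fell (8 and 11 when adjusted over the list alone), with a median of -0.02, a mean of 0.12 and no call (adjusted p = 0.974). Mmp11, a stromal protease gene, rose by 1.59 while Col6a3 of collagen VI fell by 0.80. Of 10 Schwann and nerve markers 2 rose and 3 fell (2 and 4 when adjusted over the list alone), with S100b at -1.34 and the transcription factor gene Sox10 at 0.84. Of 28 duct growth factors and receptors 4 rose and 2 fell (5 and 2 when adjusted over the list alone), with Egfr at 1.33, Fgf7 at -1.28 and Bmp4 at -1.28. Mmp11, Col6a3 and Sox10 lost the call with tissue marker covariates and with the beta-actin covariate. S100b, Egfr, Fgf7 and Bmp4 kept it under every setting. In females at 10, 0 of the fibroblast and matrix genes passed in limma or when adjusted over the list alone.

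Hepatocyte transcripts appeared in 5 arrays of 4 groups. A further list of liver genes, whose values had not been looked at when it was written, had means of 1.42, 0.36, 0.49, 1.20 and 0.31 in these arrays, lowest at 0.31, against at most -0.01 in the other arrays. RNA from hepatocytes, carried over in handling, may be the source. Estradiol dose as the whole cause is argued against, since the 3 male arrays at 0 had the same dose and spanned 3.33 in the score by which the arrays were found. In the further list they had -0.12, 0.49 and 1.20.

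White adipocyte markers were lower in males at 10, with a median of -1.36. A lower share of adipocytes alone, which would raise markers of every other cell type alike, is argued against by the endothelial median of -0.40, with 9 of 16 lower. A lower share of adipocytes and endothelial cells together was not tested. Muscle, lymphocyte and hepatocyte RNA as the whole cause is argued against by a median of -1.24 with these marker scores as covariates. Skin RNA was not in that fit. Keratinocyte markers averaged -0.50, -0.46 and -0.17 in males at 0 and 0.66, 1.63 and 0.64 at 10. RNA quality as the whole cause is argued against only so far as beta-actin measures it, by a median of -1.04 with that covariate. In males the actin difference was higher in each array at 10 than in each at 0, so a part played by RNA quality cannot be told apart. Below 10 it did not follow dose, at -0.36, -0.50 and -0.47 at 0.1 and -0.24, -0.36 and -0.15 at 1. Effects of the estradiol dose on fat cells or on other cells of the gland stay open, and no test here separates them.

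Of 100 regroupings of the arrays by dose within each sex, 8 gave as many list calls as the real 99, and the highest other gave 114, so chance is not excluded for the number of list calls. The median of the regroupings was 77. List calls at the preset correlation may therefore come largely from tissue differences between single arrays, and 3 of the 99 passed with an estimated correlation.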
